A study of Mus musculus with 10 samples.

How the data were processed

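Liver total RNA of 6 Tgfbr2+/- mice and 4 wild-type littermates was hybridised to 2-colour oligonucleotide arrays, 1 array value column per mouse, against a reference pool of liver RNA from 6 wild-type mice. Per the labels' protocols, RNA was purified on Qiagen RNeasy columns with DNase treatment and amplified on a customised robotic workflow with MessageAmp II aminoallyl chemistry. The labels give Cy3 for the first channel and Cy5 for the second, and name the pool first in each title. The series design text states that dye swaps were part of the profiling. Whether a deposited column joins a dye-swapped pair of arrays is not given in the sources used here, nor are the scanner software, the background correction and the normalization.

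The deposited values are ratios of sample and pool on a log scale, taken here as log10. The base was inferred from the values: 8 of them lie at exactly 2 or -2, a limit of 100-fold on the log10 scale. Column medians of the deposited log10 ratios lay between 0.0013 and 0.0047, so the columns are centred close to 0. All values were multiplied by 3.32 to give log2 ratios, with no further normalization, and no value was missing.

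The direction of the ratio is likely sample over pool. This rests on the order of the channels in the titles and on the Tgfbr2 probe that differed between the groups, which was lower in 5 of the 6 heterozygous libraries. Scale and direction are thus inferred and stay unknown from the labels, while the centring can be read from the values. If all columns run the other way, every difference given here changes sign. Pearson correlations between libraries over all probes ranged from -0.32 to 0.52. The lowest was that of wild-type replicate 1 with Tgfbr2+/- replicate 5, where Spearman's rho was -0.35, so either column could be turned. On the acute phase list wild-type replicate 1 was at -0.40 and the other wild-type libraries at -0.40 to -0.19. Its Moxd1 and Saa3, picked for lying below the pool in all wild-type libraries, were at -5.18 and -3.40. The others were at -4.84 to -4.64 and -3.32 to -2.36. The acute phase values, from a list fixed in advance, argue against a turned wild-type replicate 1. Those of Moxd1 and Saa3 do not count, since their selection required this library to lie below the pool. The direction of Tgfbr2+/- replicate 5 is not settled. The limma, camera and window tests were therefore repeated with the sign of each of these 2 columns turned, as were the exact tests of the macrophage list's mean and of its difference from 5 other cell-type lists. The fits with a fasting score were not.

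The table holds 23438 probes. In the platform annotation 17726 probes carry 1 gene symbol, 50 carry several and 5662 are unnamed here. Probes with several symbols were tested but not named. Probes with the same symbol were averaged to 16383 genes. Of the 1142 genes with over 1 probe, 501 had probes whose differences had opposite signs. No symbol changed when Entrez identifiers were looked up in the RefSeq gene table. That table, of assembly GRCm38.p6, was used only for names and for which genes neighbour Tgfbr2, and 17627 of the probes had a position through it.

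Groups were taken from the sample titles. Differences between the 6 Tgfbr2+/- and 4 wild-type libraries were fitted per probe with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, and Benjamini-Hochberg adjusted over all probes, with a threshold of 0.05. The same fit gave each group's mean against 0, that is, against the pool. That test leaves out the pool's own spread and any dye bias. Single values were compared with an exact two-sided permutation test over all 210 splits of 10 libraries into 4 and 6, whose smallest p is 0.0048. Before the data were examined, 38 gene lists were fixed (pathways, liver cell types, cell types of neighbouring tissues, and sex-biased genes). Of these, 37 had at least 5 measured members and were tested at the gene level with limma's camera at a preset correlation of 0.01. The remaining list, genes of X inactivation, had no measured member. Genes within 10 Mb of Tgfbr2 were compared with all others by Fisher's exact test.

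The named genes follow a rule fixed in advance. It takes Tgfbr2, then 12 genes per direction by probe, filled by the smallest unadjusted p where fewer pass the threshold, and the 4 members of smallest p in each list. Genes outside it are marked as chosen after their values were seen. A second, shorter list of fasting-induced genes was written only after the values had been seen, and is used only among the closing observations.

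On data simulated with the spread of these libraries, the probe test called 74% of 50 probes changed by 0.5 on the log2 scale, 98% of those changed by 1 and 100% of those changed by 2 or 4. It called 12 of 23238 unchanged probes. All changed probes were put into the same data set with independent noise, so the larger changes eased the adjusted threshold for the smaller ones. The 74% therefore need not hold for data with few changed probes. The camera test called a list of 28 genes shifted by 0.25 and 0 of 35 other lists. The simulation draws genes independently and so does not show how camera behaves when the members of a list vary together.

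Alternatives fixed in advance were median centring of each array, quantile normalization, array weights, robust eBayes, leaving out each library in turn, the replicate number as a block, keeping the probes in the upper part of the SD distribution, genes in place of probes, an adjusted p of 0.10, the most variable probe per gene, an estimated correlation in camera, limma's fry, the heterozygous mean against the pool, and windows of 5 and 20 Mb. The turned signs, leaving out Tgfbr2+/- replicates 4 and 5 together, and an exact permutation test of list means were added after the data had been seen. Scanner intensities were not used here, so dim or saturated probes could not be set apart. The number of arrays limits the precision: the median standard error of a probe's difference was 0.07 on the log2 scale. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.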

Results

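Liver expression profiles were compared between mice with 1 inactivated copy of Tgfbr2, the gene of the type II receptor for TGF-beta, and wild-type littermates, to ask what the loss of a copy changes in liver on a chow diet. The data hold 10 libraries, 6 Tgfbr2+/- and 4 wild type, each a log ratio against a pool of wild-type liver RNA. The titles of the heterozygous libraries name males, and those of the wild-type libraries state no sex. Values are log2 ratios over the pool as mean ± SD, and differences are Tgfbr2+/- minus wild type, ± SE. The direction of the ratio, sample over pool, is likely but not settled by the labels, and every "higher" or "lower" here rests on it.

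Tgfbr2 itself was lower in 5 of the 6 heterozygous libraries on 1 of its 2 probes. The direction of the ratio was inferred partly from this probe, so that the groups differ is a result and that Tgfbr2 is the lower is in part assumed. On probe 10024401828 the heterozygous libraries averaged -0.70 ± 0.48 (SD, n = 6) and the wild-type libraries 0.17 ± 0.43 (SD, n = 4), a difference of -0.88 ± 0.26, or 1.84-fold lower (exact permutation p = 0.0286, limma adjusted p = 0.757). The heterozygous values were -0.82, -1.11, -1.04, 0.20, -0.86 and -0.60 for replicates 1 to 6. The library labelled Tgfbr2+/- replicate 4, at 0.20, lay within the wild-type range of -0.29 to 0.64, so this probe goes against its label. The second probe, 10024408236, differed by -0.07 ± 0.09 (exact permutation p = 0.457). Which part of the transcript either probe reads, and whether the mutant allele lacks it, is not given in the sources used here. The mean of both probes differed by -0.47 ± 0.12 (exact permutation p = 0.0143, limma adjusted p over all genes = 0.516). With the sign of wild-type replicate 1 turned that difference was -0.36, and with that of Tgfbr2+/- replicate 5 turned it was -0.31 and limma's unadjusted p rose from 0.00216 to 0.110.

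**Figure D1:**
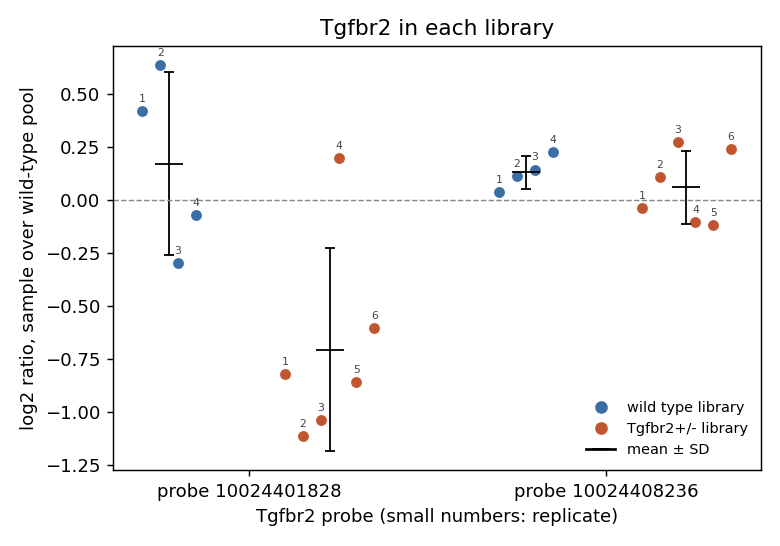
Log2 ratio over the wild-type pool (vertical axis) of both Tgfbr2 probes (horizontal axis) in each library, numbered by replicate, with the group mean and SD. On probe 10024401828, 5 heterozygous libraries lie between -1.11 and -0.60, and replicate 4 lies at 0.20.

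Of the 12 genes with the smallest p that were higher in heterozygous liver, 6 belong to the list of Kupffer cell and macrophage markers (Vsig4, Cd5l, Folr2, Tyrobp, Adgre1 and Clec4f), and none of the 12 passed the adjusted threshold. They were Vsig4 (0.52 ± 0.07), a complement receptor of Kupffer cells, the resident macrophages of liver, Pilra (0.69 ± 0.09), Cd5l (0.67 ± 0.10), Pla2g4a (0.48 ± 0.07), the lysosomal protease Ctss (0.58 ± 0.09), Pcolce2 (0.58 ± 0.09), the folate receptor Folr2 (0.61 ± 0.10), Plek (0.44 ± 0.07), the adaptor Tyrobp (0.43 ± 0.07), Adgre1, which encodes the macrophage antigen F4/80 (0.49 ± 0.08), Adgre5 (0.40 ± 0.07) and Clec4f (0.43 ± 0.08). For each of these 12 genes all 6 heterozygous libraries lay above all 4 wild-type libraries. Selection by the smallest p between these groups favours that, so it adds no support. Limma's adjusted p ranged from 0.129 for Vsig4 to 0.252 for Clec4f. The genes of smallest p in the other direction, which did not pass either, were Vmn1r18 (-0.38 ± 0.07), 2700097O09Rik (-0.25 ± 0.05), Dancr (-0.34 ± 0.07), Blm (-0.26 ± 0.06), Smad5 (-0.27 ± 0.06), a transducer of BMP signals, Sult2b1 (-0.45 ± 0.10), Tbce (-0.18 ± 0.04), Zmiz1 (-0.31 ± 0.07), Qrich2 (-0.24 ± 0.06), Cyp4a14 (-0.48 ± 0.12), Olfr125 (-0.37 ± 0.09) and Gstt3 (-0.64 ± 0.16).

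By limma, 0 of 23438 probes passed an adjusted p of 0.05, and 0 of 16383 genes did. At an unadjusted p under 0.05 there were 1151 probes, 559 higher and 592 lower, where 1171.9 are due by chance. At an unadjusted p under 0.01 there were 280, 167 higher and 113 lower, against 234.38 by chance. That count was 149 without wild-type replicate 1, 181 without wild-type replicate 3 and 466 without wild-type replicate 4, and 131 or 121 with wild-type replicate 1 or Tgfbr2+/- replicate 5 turned in sign. The groups did not overlap for 222 probes, 0.947% of all, and chance gives 0.952%. Without Tgfbr2+/- replicate 3, 15 probes passed the adjusted threshold, among them those of Vsig4, Pilra, Cd5l, Ctss, Pcolce2 and Tyrobp. With the sign of wild-type replicate 1 or of Tgfbr2+/- replicate 5 turned, 0 probes passed.

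The list of Kupffer cell and macrophage markers was higher in heterozygous liver. Of its 28 measured genes 23 had positive differences, 18 passed when adjusted over the list alone, all of them higher, and 0 passed over all genes. The mean difference was 0.26, or 1.20-fold (camera adjusted p = 1.26e-21). Cd5l, Vsig4 (0.48 ± 0.08 as the mean of its probes), Folr2, Tyrobp, Adgre1 and Clec4f were among the 18, as were, chosen after their values were seen, the complement gene C1qc (0.39 ± 0.07), the Fc receptor Fcgr1 (0.54 ± 0.10) and the ficolin Fcna (0.50 ± 0.11). Marco (-0.17 ± 0.37), Cd163 (-0.05 ± 0.22) and Cd68 (0.03 ± 0.04), also chosen after their values were seen, did not pass. The list's mean log2 ratio was -0.13 ± 0.02 in wild type (SD, n = 4) and 0.13 ± 0.08 in Tgfbr2+/- (SD, n = 6), so the wild-type libraries lay below the wild-type pool by about as much as the heterozygous ones lay above it. All 6 heterozygous libraries were above all 4 wild-type ones, the nearest being Tgfbr2+/- replicate 3 at -0.01. The call held with an estimated correlation (adjusted p = 0.0292) and with fry (adjusted p = 0.00402). The exact permutation p of the list mean was 0.0048, the smallest that 210 splits can give, and 0.0881 after adjustment over 37 lists. With wild-type replicate 1 or Tgfbr2+/- replicate 5 turned in sign the mean difference was 0.21 or 0.22 (exact permutation p = 0.0190 or 0.0238).

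**Figure D2:**
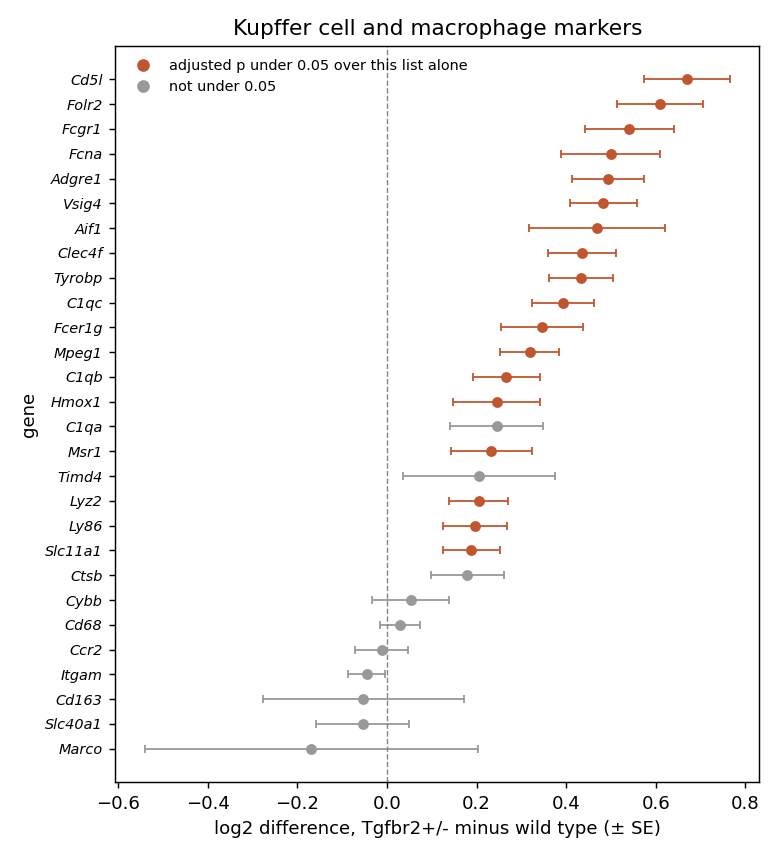
Log2 difference, Tgfbr2+/- minus wild type, with its SE (horizontal axis) for the 28 measured genes of the Kupffer cell and macrophage list (vertical axis). The 18 genes that pass when adjusted over the list alone are all higher, and Cd5l is the highest at 0.67.

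Markers of most other liver cell types differed less than those of macrophages. The neutrophil list was higher by 0.12 (16 of 18 genes positive, camera adjusted p = 0.000153), with S100a9 (0.79 ± 0.18) the gene that passed over the list alone, and all 6 heterozygous libraries above all 4 wild-type ones. Its adjusted p was 0.0718 with an estimated correlation. Endothelial markers differed by 0.02, stellate and fibroblast markers by -0.01, hepatocyte markers by -0.04, lymphocyte markers by 0.06 and erythroid markers by -0.01, with camera adjusted p from 0.0603 for lymphocytes to 0.748 for erythroid cells. The lymphocyte list passed without wild-type replicate 4 (0.08, adjusted p = 0.0130) and without Tgfbr2+/- replicate 2, 3 or 5 (0.06, 0.08 and 0.07, adjusted p = 0.0467, 0.00957 and 0.0271). It also passed with array weights (adjusted p = 0.0364) and against the pool (adjusted p = 0.0188), and its adjusted p reached 0.548 over the other alternatives. In heterozygous liver the hepatocyte list (-0.08, adjusted p = 0.0234) and the periportal list (-0.09, adjusted p = 0.00660) passed as lower than the pool. Wild type lay below the pool too, at -0.04 and -0.08. Between the groups the periportal list differed by -0.01 (camera adjusted p = 0.474) and the hepatocyte list did not pass either (camera adjusted p = 0.484). The macrophage shift exceeded the endothelial one by 0.24, the stellate one by 0.28, the hepatocyte one by 0.30 and the lymphocyte one by 0.21, each with an exact permutation p of 0.0048 (0.0103 after adjustment over 13 cell-type lists). With wild-type replicate 1 turned in sign the excess over stellate markers was 0.15 (exact permutation p = 0.110). It exceeded the neutrophil shift by 0.15 (exact permutation p = 0.0476, adjusted p = 0.0516). For stellate markers the mean was negative, and the median and the camera direction were positive. For erythroid markers the mean and median were negative and the camera direction was positive.

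Interferon-stimulated genes were higher, with positive differences for 34 of 37, a mean of 0.23 (camera adjusted p = 2.65e-15, adjusted p = 0.178 with an estimated correlation) and 8 genes past the threshold over the list alone. These included Ifi27l2a (0.83 ± 0.17), the transcription factor Irf7 (0.53 ± 0.11), Ifit2 (0.48 ± 0.11) and Lgals3bp (0.26 ± 0.07). The list lay above all wild-type libraries in 5 of 6 heterozygous libraries, and Tgfbr2+/- replicate 3 was at -0.18. MHC class II presentation genes were higher by 0.14 (9 of 10 positive, camera adjusted p = 0.000693), with Ctss the gene that passed over the list alone and H2-Ab1 at 0.17 ± 0.07. With an estimated correlation the adjusted p was 0.388. The call was also lost with wild-type replicate 1 or Tgfbr2+/- replicate 5 turned in sign (0.08 and 0.09, adjusted p = 0.0713 and 0.155) and without Tgfbr2+/- replicates 4 and 5 together (0.10, adjusted p = 0.0820). Acute phase genes were higher by 0.13 (camera adjusted p = 0.0465), with Serpina10 at 0.30 ± 0.10 and Hpx at 0.36 ± 0.15. That call was lost when wild-type replicate 1, 3 or 4 or Tgfbr2+/- replicate 4 or 5 was left out (adjusted p = 0.0642, 0.105, 0.274, 0.141 and 0.449), and with an estimated correlation (adjusted p = 0.645). Without Tgfbr2+/- replicate 5 its mean difference was 0.03. The list's mean log2 ratio was 0.29 in that library and -0.01 in the library labelled Tgfbr2+/- replicate 4, against -0.48 to -0.32 in the other 4 heterozygous libraries, so these 2 carry the difference.

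Genes induced through the xenobiotic receptors CAR and PXR were lower in heterozygous liver, with negative differences for 28 of 32, a mean of -0.30 (camera adjusted p = 7.81e-08, adjusted p = 0.206 with an estimated correlation) and 7 genes past the threshold over the list alone. Cyp2b9 differed by -1.86 ± 0.52 (3.63-fold lower), Cyp2b10 by -0.98 ± 0.27 (1.97-fold lower), Sult1d1 by -0.66 ± 0.17 and Gstt3 by -0.64 ± 0.16. Cyp2b13, chosen after its values were seen, differed by -1.53 ± 0.47. Female-biased liver genes were also lower, with a mean difference of -0.29 (30 of 41 negative, 4 past over the list alone, camera adjusted p = 2.59e-06, adjusted p = 0.121 with an estimated correlation). The 4 were Cyp2b9, Cyp2b10, Gstt3 and Cyp4a14, and 7 genes belong to both lists. With Tgfbr2+/- replicate 5 turned in sign both lists lost their calls, at -0.14 each (camera adjusted p = 0.163 for CAR and PXR, 0.273 for female-biased genes). Wild-type replicate 4 overlapped the heterozygous libraries, with Cyp2b9 at -1.42. Male-biased genes were higher by 0.26 (23 of 32 positive, camera adjusted p = 0.00141, adjusted p = 0.467 with an estimated correlation), with Moxd1 at 3.18 ± 1.24, Ugt2b38 at 1.48 ± 0.51, the oxysterol hydroxylase Cyp7b1 at 0.46 ± 0.17 and Alas2 at 0.15 ± 0.05. No male-biased gene passed over the list alone, and Moxd1 lay at the wild-type level in Tgfbr2+/- replicates 3 and 6 (-4.50 and -4.81, wild-type mean -4.84). The call of the list was lost with wild-type replicate 1 or Tgfbr2+/- replicate 5 turned in sign (0.10 and 0.15, adjusted p = 0.0857 and 0.155) and against the pool (0.04, adjusted p = 0.0680). The 5 measured Y-linked genes differed by -0.02 on average (camera adjusted p = 0.636).

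**Figure D3:**
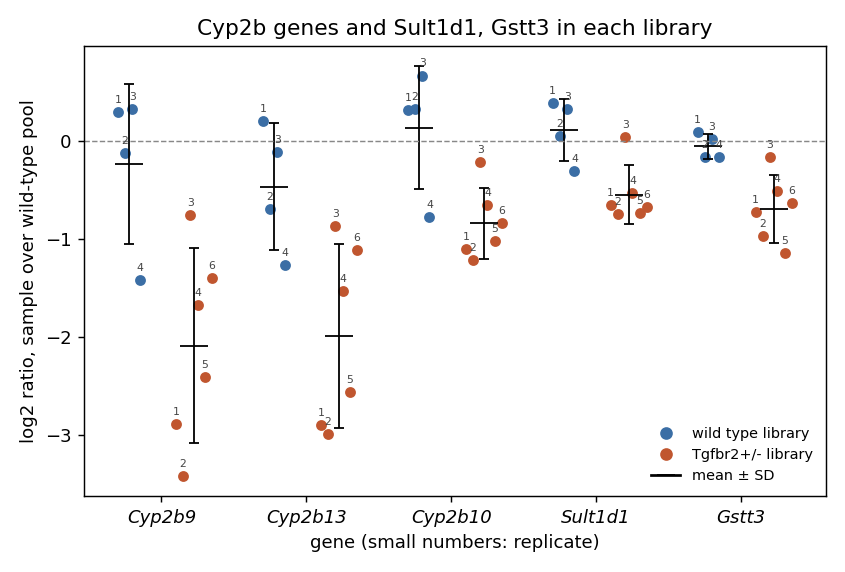
Log2 ratio over the wild-type pool (vertical axis) of Cyp2b9, Cyp2b13, Cyp2b10, Sult1d1 and Gstt3 (horizontal axis) in each library, numbered by replicate, with the group mean and SD. Cyp2b9 lies between -3.42 and -0.75 in the heterozygous libraries and between -1.42 and 0.32 in wild type.

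Among lists of lipid and energy metabolism, cholesterol synthesis genes were higher by 0.14 (20 of 22 positive, camera adjusted p = 2.59e-06, adjusted p = 0.388 with an estimated correlation), with the sterol enzymes Fdft1 (0.38 ± 0.10), Msmo1 (0.57 ± 0.20) and Mvd (0.23 ± 0.08) and the regulator Insig1 (0.37 ± 0.15). Wild-type replicate 1, at -0.35 against -0.06 to 0.05 in the other 3 wild-type libraries, carries most of this difference, which was 0.06 without it (adjusted p = 0.00700) and -0.04 with its sign turned. Against the pool the heterozygous mean was 0.04 (adjusted p = 0.0800). Targets of PPAR-alpha and genes of fatty acid oxidation were lower by a mean of -0.17 (31 of 39 negative, camera adjusted p = 7.22e-05, adjusted p = 0.378 with an estimated correlation), with Cyp4a14 and Cyp4a31 (-0.48 ± 0.15) among them, while Fabp1 (0.54 ± 0.18) and Ppara (0.18 ± 0.06) had positive differences. Oxidative phosphorylation genes were lower by a mean of -0.06 (41 of 44 negative, camera adjusted p = 0.00027, adjusted p = 0.475 with an estimated correlation) and those of the tricarboxylic acid cycle by a mean of -0.05 (20 of 26 negative, camera adjusted p = 0.00702, adjusted p = 0.467 with an estimated correlation). Cell cycle genes were higher by 0.06 (36 of 47 positive, camera adjusted p = 0.00313, adjusted p = 0.475 with an estimated correlation). No member of these 5 lists passed over its list alone. Oxidative phosphorylation lost its call without Tgfbr2+/- replicate 5 (-0.03, adjusted p = 0.0710) and with wild-type replicate 1 turned in sign (adjusted p = 0.0857). Cell cycle lost it without wild-type replicate 2 (0.05, adjusted p = 0.0554), with array weights (adjusted p = 0.129) and without Tgfbr2+/- replicates 4 and 5 together (adjusted p = 0.108). The tricarboxylic acid cycle lost it without wild-type replicate 2 (-0.03, adjusted p = 0.102) or Tgfbr2+/- replicate 2 (-0.03, adjusted p = 0.0704).

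In all, 13 of 37 lists passed camera at the preset correlation, 8 higher and 5 lower. Of these, 1 held with an estimated correlation, 1 with fry and 0 by exact permutation of the list mean, the first 2 counts both being the macrophage list. With Tgfbr2+/- replicate 5 turned in sign 3 lists passed, those of macrophages, interferon-stimulated genes and cholesterol synthesis, and with wild-type replicate 1 turned 8 of the 13 held, 5 were lost and 4 others passed. Of 100 splits of the libraries, 11 gave at least 13 lists, so the number of lists is within what other groupings give.

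**Figure D4:**
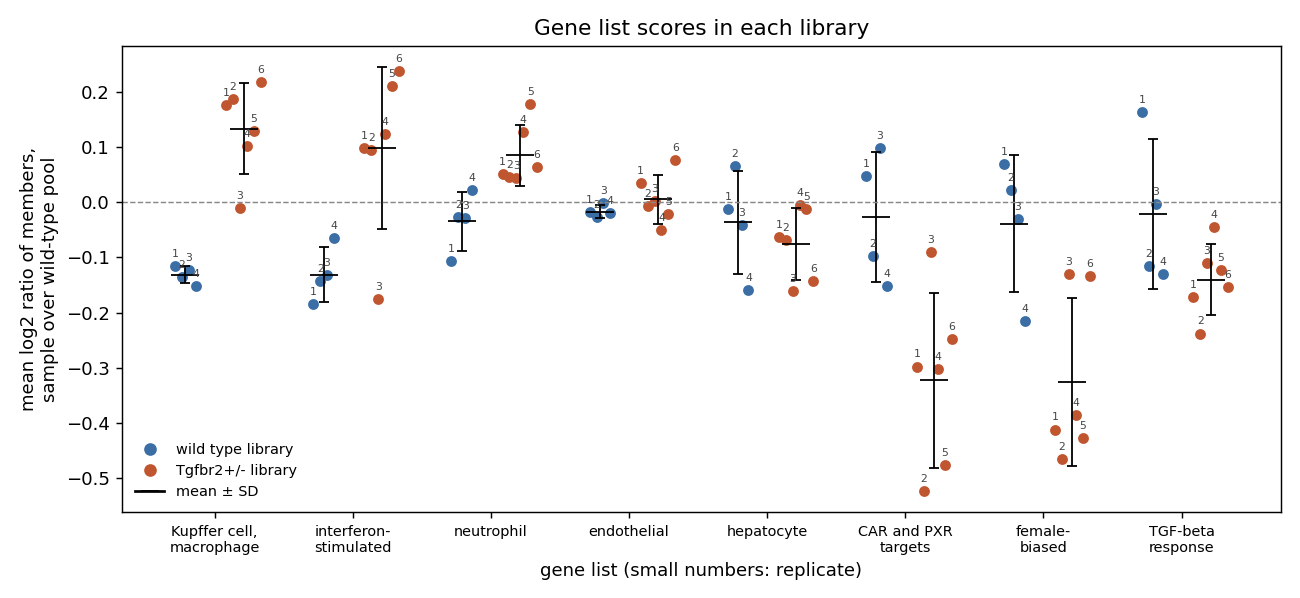
Mean log2 ratio over the wild-type pool (vertical axis) of the members of 8 gene lists (horizontal axis) in each library, numbered by replicate, with the group mean and SD. The macrophage scores of the groups do not overlap, while the hepatocyte, endothelial and TGF-beta response scores do.

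The lists of genes tied to TGF-beta signalling did not pass with all 10 libraries, and that of TGF-beta response genes passed when some were left out. The family of ligands, receptors and Smads differed by a mean of -0.001 (camera adjusted p = 0.936), with Tgfbr2 and Smad5 (-0.21 ± 0.05 over both of its probes) past the threshold over the list alone, and the list's mean and median had opposite signs. TGF-beta response genes differed by a mean of -0.12 (19 of 29 negative, camera adjusted p = 0.129) and a median of -0.03. Members with large differences thus carry much of the mean. Klf10 was at -0.65 ± 0.22, Cdkn1a at -0.36 ± 0.14, Postn at -0.32 ± 0.14 and Tgfbi at 0.19 ± 0.09. The response list was lower without wild-type replicate 2 (-0.15, adjusted p = 0.0395), without Tgfbr2+/- replicate 5 (-0.12, adjusted p = 0.0471), without Tgfbr2+/- replicates 4 and 5 together (-0.15, adjusted p = 0.0139) and against the pool (-0.14, adjusted p = 0.0151). It differed by -0.06 without wild-type replicate 1 (adjusted p = 0.655), and its adjusted p was 0.475 with an estimated correlation. Collagens and other matrix genes differed by -0.02 (20 of 41 positive, camera adjusted p = 0.979, with a positive camera direction), with Col5a3 at 0.38 ± 0.09.

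Each group was also set against the pool of wild-type liver. In heterozygous liver 1 probe passed, that of Hao2, a peroxisomal hydroxyacid oxidase (-1.02 ± 0.11, limma adjusted p = 0.0377), which was also below the pool in wild type (-0.48 ± 0.14). The difference between the groups for Hao2 was -0.53 ± 0.17 (limma adjusted p = 0.732). At an unadjusted p under 0.05 there were 4107 probes in heterozygous liver (n = 6) and 994 in wild type (n = 4), where 1171.9 are due by chance in each. The direct comparison of the groups gave 1151, so these counts do not measure a difference between the groups. In wild type limma's adjusted count was 0 and its smallest adjusted p 0.994. In 7 of the 10 fits that left out 1 library 0 probes passed in heterozygous liver, 54 passed without Tgfbr2+/- replicate 3, and 0 passed with Tgfbr2+/- replicate 5 turned in sign. With wild-type replicate 1 turned the counts stayed 1 and 0.

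Genes near Tgfbr2 on chromosome 9 were examined because a targeted allele can carry flanking DNA of the strain in which it was made. Of 226 genes within 10 Mb on either side, 11 (4.87%) had an unadjusted p under 0.05, against 891 of 16064 other genes (5.55%), an odds ratio of 0.871 (Fisher's exact p = 0.770). The 11 included, chosen after their values were seen, Shisa5 (0.23 ± 0.07), Itga9 (0.38 ± 0.16) and Sec22c (-0.18 ± 0.07). Without Tgfbr2+/- replicate 5 the odds ratio was 0.403 (Fisher's exact p = 0.0349), and it was above 1 without wild-type replicate 2, at 1.25, and in the 5 Mb window, at 1.90. With wild-type replicate 1 or Tgfbr2+/- replicate 5 turned in sign it was 0.485 or 0.414.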

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

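The tests of explanations in this part were chosen after the patterns had been seen, except the counts over other splits of the libraries for probes, lists and genes near Tgfbr2, which were fixed before those counts were made. Each named gene and list score was checked within each group for a library far from the others, by the gap to its neighbour as a share of the group's range. Of 382 checks 19 stood out, and chance, at 1 in 20, gives about 19.1, so the pattern of single libraries carries no excess.

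In wild type, replicate 4 stood apart most often, in 7 results. It was lowest for Sult2b1 (-0.13, share 0.991), Loxl2 (0.02, share 0.878) and Lpin1 (-2.12 against 0.63 to 0.88, share 0.916). It was highest for Hspa5 (0.23, share 0.915), S100a9 (0.13, share 0.887), Stab2 (0.10, share 0.928) and the pericentral hepatocyte score (0.14, share 0.990). Wild-type replicate 1 was lowest for Cldn7 (-0.14, share 0.907) and Car5b (-0.29, share 0.854) and highest for the Y-linked score (0.05, share 0.869). Wild-type replicate 2 was lowest for Tyrobp (-0.22, share 0.857) and highest for the acute phase score (-0.19, share 0.972), and replicate 3 was highest for Smad5 (0.35, share 0.839). In the heterozygous group, replicate 3 was lowest for Pilra (0.12, share 0.638), Acsl3 (-0.23, share 0.646) and the interferon score (-0.18, share 0.651) and highest for Sult1d1 (0.05, share 0.733). Replicate 5 was highest for Ppp1r3g (0.37, share 0.870) and the periportal score (0.19, share 0.848).

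For the higher macrophage markers in heterozygous liver, a lower share of hepatocytes would raise endothelial and stellate markers alike. The macrophage shift exceeded the endothelial one by 0.24 on the log2 scale (exact permutation p = 0.0048, and 0.00952 or 0.0429 with wild-type replicate 1 or Tgfbr2+/- replicate 5 turned in sign). It exceeded the stellate one by 0.28 (exact permutation p = 0.0048, and 0.110 or 0.0476 with these signs turned). More blood in the samples would raise erythroid and lymphocyte markers at least as much. The macrophage shift exceeded the erythroid one by 0.27 (exact permutation p = 0.00952, and 0.0190 or 0.0571 with these signs turned). It exceeded the lymphocyte one by 0.21 (exact permutation p = 0.0048, and 0.0143 or 0.0238 with these signs turned). Neutrophil markers were themselves higher by 0.12, and the macrophage excess over them was 0.15 (exact permutation p = 0.0476, adjusted p = 0.0516). Blood was thus weighed by red cells and lymphocytes, and its neutrophils were not set apart. With a score of fasting-induced genes as a covariate the macrophage difference was 0.26, with a 95% interval of 0.13 to 0.38. Without wild-type replicate 4 this covariate fit gave 0.15 (-0.09 to 0.39), so feeding state stays open. Genotype stays open as untested, as does a shared cage or day within a group, which the labels do not give, and the wild-type libraries also lay below their own pool.

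For the lower female-biased and Cyp2b genes, wild-type libraries of the other sex were assumed to shift the male-biased list by at least 1 on the log2 scale. That bound was chosen after the pattern had been seen, and the list's median shift was 0.12. The bound does not address wild-type libraries of mixed sex. The mean of the Y-linked genes lay between -0.08 and 0.05 in all 10 libraries, and between 0.01 and 0.05 in wild type. If these probes read above background, the values argue against wild-type libraries of the other sex or of mixed sex. Signal over background was not used here, so that condition could not be checked. Feeding state stays open: with the fasting score as a covariate the female-biased difference went from -0.29 to -0.18, with a 95% interval of -0.40 to 0.03, and it was -0.06 (-0.55 to 0.43) without wild-type replicate 4, -0.23 (-0.46 to -0.01) without Tgfbr2+/- replicate 3 and -0.22 (-0.41 to -0.03) without Tgfbr2+/- replicate 6. A bound of 2 standard errors, written first, would have excluded feeding state, since the value lay -2.05 standard errors from 0. It was replaced after that result was seen, because with 7 residual degrees of freedom the 95% interval is wider, and feeding state cannot be told apart from genotype here.

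The Tgfbr2 level of the library labelled Tgfbr2+/- replicate 4 was weighed last. A swap with a wild-type library needs a partner among them, and the lowest wild-type value was -0.29, outside the -1.11 to -0.60 of the other heterozygous libraries. A wild-type mouse under the heterozygous label cannot be told apart from a heterozygous one. The library's macrophage score, 0.10, lay outside the wild-type range of -0.15 to -0.12 and within that of the other 5. Its female-biased score, -0.39, also lay outside the wild-type range, -0.22 to 0.07. Both bear on genotype only if these differences follow genotype and not feeding state or a shared cage or day. On the second Tgfbr2 probe it was at -0.10, below the wild-type values of 0.04 to 0.23, but that probe did not separate the groups (exact permutation p = 0.457).

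Splits of the libraries, 100 of the 210 with the real one included, were counted for each result. For probes past the adjusted threshold the count says nothing, since the real split gave 0 and all 100 give at least that (highest other 37). Chance could not be excluded for the next 3 counts. For probes, 21 splits gave at least 280 with an unadjusted p under 0.01 (highest other 1067). A split with several times the real count points to structure among the libraries other than genotype. For lists, 11 of the 100 splits gave at least 13 past camera's threshold (highest other 17), and the median of the other splits was 6. For genes near Tgfbr2, 38 splits gave at least 11 (highest other 43). For the smallest camera p of any list, 1 split of 100, the real one, reached 3.39e-23. This statistic was chosen after the macrophage list had been seen and so decides nothing about chance. That list's mean had an exact permutation adjusted p of 0.0881, reached from the smallest exact p that the 210 splits can give. The next was 1.64e-20, or 19.8 as a negative log10. That split kept wild-type replicates 1, 2 and 4 together with Tgfbr2+/- replicate 3, so it holds much of the real difference. A split that put wild-type replicates 1 and 3 with Tgfbr2+/- replicates 2 and 5 still gave a negative log10 of 17.3. Camera's p at the preset correlation is thus far too small as a measure of chance.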

How the results depend on the processing

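The omission of Tgfbr2+/- replicates 4 and 5 together, the turned signs and the exact permutation of list means were tests chosen after the results had been seen, and the other alternatives were fixed before. Median centring, quantile normalization and robust eBayes moved no result on probes, on Tgfbr2 or on the window, and quantile normalization ended the call of 1 list, the tricarboxylic acid cycle (-0.030). Robust eBayes was not run for lists. Signal over background was not used here.

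Heterozygous liver against the pool gave 2 probes with array weights, 10 in the upper part of the SD distribution, 0 with replicate 5 turned in sign, 4 without replicates 4 and 5, and 0 to 54 with 1 library left out. Wild type against the pool gave 6 without Tgfbr2+/- replicates 4 and 5 and 0 to 1 with 1 library left out. The comparison of the groups gave 0 to 15 with 1 library left out, and 0 under every other alternative. At an unadjusted p under 0.01 it gave 149 to 466 with 1 library left out, 165 in the upper part of the SD distribution, 131 with wild-type replicate 1 turned and 121 with Tgfbr2+/- replicate 5 turned, against 280. Lists past the threshold numbered 13 at the preset correlation, 1 with an estimated correlation, 1 with fry, 0 by exact permutation (the macrophage mean stays 0.26, adjusted p = 0.0881), 3 with Tgfbr2+/- replicate 5 turned, and 12 to 14 with 1 library left out. The Tgfbr2 level differed by -0.40 to -0.55 with 1 library left out and by -0.31 with replicate 5 turned, where limma's unadjusted p was 0.110. The odds ratio near Tgfbr2 was 1.90 in the 5 Mb window, 1.22 with the block, and 0.403 to 1.25 with 1 library left out. The cause was not tested for any of these.

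For lists, direction means that of camera or fry, which can differ from the sign of the mean given here. Camera's direction turned with array weights for collagens (-0.031), the insulin axis (-0.00045), pericentral genes (0.034) and stellate markers (-0.041). Against the pool it turned for collagens (-0.057), acute phase (-0.21), the insulin axis (0.0018), Y-linked genes (0.0029), endothelial (0.0055), stellate (-0.047), erythroid (-0.036) and muscle markers (0.013). With wild-type replicate 1 turned in sign it turned for cholesterol synthesis (-0.036), immediate-early genes (-0.014) and endothelial markers (0.013), and the acute phase mean became -0.070 and lost its call. With Tgfbr2+/- replicate 5 turned it did so for collagens (-0.019), fatty acid synthesis (0.0095), bile acid genes (-0.011), oxidative phosphorylation (0.0040), NRF2 targets (0.0052), the insulin axis (-0.017), pericentral genes (0.041) and gut markers (-0.018). Without replicates 4 and 5 it did so for collagens (-0.048), acute phase (-0.046), pericentral genes (0.016) and stellate markers (-0.045). With fry it did so for the TGF-beta family (-0.0014). Of these lists only those of cholesterol synthesis, acute phase and oxidative phosphorylation had passed.

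With 1 library left out the direction turned in at least 1 fit, over the ranges given, for the TGF-beta family (-0.024 to 0.015), collagens (-0.048 to 0.042), fatty acid synthesis (-0.17 to -0.062), NRF2 targets (-0.072 to -0.020), the insulin axis (-0.0029 to 0.032), Y-linked genes (-0.030 to -0.0041), hepatocyte (-0.079 to -0.0045), pericentral (-0.056 to 0.034), endothelial (0.0086 to 0.034) and erythroid markers (-0.046 to 0.022). Tgfbr2 probe 10024408236 turned against the pool (0.062) and without replicates 4 and 5 (0.015). Usp9y turned with array weights (0.033), with the block (0.085), with wild-type replicate 1 turned (0.030), with Tgfbr2+/- replicate 5 turned (0.062), without replicates 4 and 5 (0.029), and with 1 library left out (-0.055 to 0.049). Uty turned with Tgfbr2+/- replicate 5 turned (-0.022) and without replicates 4 and 5 (-0.0098), and Car5b with wild-type replicate 1 turned (-0.0082).

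The groups share replicate numbers, and the titles do not say whether these pair the libraries. Of 4 wild-type libraries 1 correlated best with its own number, and same-number correlations lay between 0.0205 and 0.300. For wild-type replicate 1 the same-number value was 0.1064 and the best 0.1069, and for replicate 2 they were 0.1009 and 0.1012. With such near ties the count does not exclude that the numbers pair the libraries or mark a shared batch. Replicates 5 and 6 exist only in the heterozygous group. With the replicate number as a block they drop out, and the difference rests on replicates 1 to 4 of each group. In that fit 0 probes and 9 of the 13 lists passed. The 4 that did not were oxidative phosphorylation (-0.0089, adjusted p = 0.562), acute phase (0.033, adjusted p = 0.239), cell cycle (0.037, adjusted p = 0.170) and the tricarboxylic acid cycle (-0.038, adjusted p = 0.0521). Camera's direction turned for collagens (-0.041), the insulin axis (-0.031), Y-linked genes (0.0026), pericentral genes (0.029), endothelial (0.012), stellate (-0.044) and erythroid markers (-0.032). The block leaves out the comparisons with the pool, which it cannot hold.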

Other observations

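The tests in this part were chosen after the values had been seen. Several genes lay far from the pool in all 4 wild-type libraries although the pool is wild-type liver. Moxd1 was 28.7-fold below the pool (-4.84 ± 0.24, SD, n = 4), Saa3 7.87-fold, Saa1 7.61-fold and Saa2 4.34-fold, and Ugt2b38 2.38-fold. In the heterozygous group these genes spread widely, with an SD of 2.84 for Moxd1, 1.88 for Saa3 and 1.91 for Saa1.

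Lpin1, a phosphatidate phosphatase induced by fasting in liver, took values of 0.63, 0.86 and 0.88 in wild-type replicates 1 to 3 and -2.12 in replicate 4. In the heterozygous libraries it ranged from -1.94 to 0.26. A mean over 16 measured fasting-induced genes was 0.00 ± 0.33 in wild type (SD, n = 4) and -0.24 ± 0.12 in Tgfbr2+/- (SD, n = 6). With all 10 libraries the exact permutation p was 0.143. Replicate 4 of wild type had the lowest score, -0.47. The other 3 wild-type libraries, at 0.03 to 0.25, lay above all 6 heterozygous ones, at -0.39 to -0.08. Without replicate 4 of wild type the difference was -0.39 in place of -0.24 (exact permutation p = 0.0119), so the result with all libraries rests on that 1 library.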
